A study of Homo sapiens with 15 samples.

How the data were processed

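The data are messenger RNA sequencing libraries of human WTC11-derived microglia-like cells at day 25 of differentiation, 5 each of isogenic control, CX3CR1 V249I heterozygous (het) and homozygous (hom) genotype. Per the labels' protocols, RNA with an integrity number of at least 7 was made into libraries with the KAPA mRNA Hyper Prep kit and sequenced on an Illumina NovaSeq instrument to about 30 M reads per library. Per the submitters' processing notes, read quality was checked with FastQC, reads were aligned to GRCh38 with STAR and reads per gene were counted with featureCounts. Tool versions, the annotation release and the settings for strand and for reads with several matches are not given in the sources used here. The deposited values are raw counts, which the whole numbers and the library sums bear out, with gene positions and the summed exon length in bases in the deposited columns. Gene symbols are those of the table. All 15 columns were matched to samples by their names, and 0 columns were left over.

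The table holds 28058 genes, 1310 of which are placed at more than 1 position. Genes were kept by filterByExpr with genotype as the group, which left 13442 genes holding at least 99.92% of the counts of each library. Library sums ranged from 16.7 to 41.2 M (median 20.6 M), so a group of 5 libraries resolves a level of about 0.0247 to 0.0292 CPM at the floor of 3 counts over the group. Libraries were scaled by TMM and fitted together, 15 libraries in 1 model without a block, with edgeR 4.0.16 (glmQLFit robust and the quasi-likelihood F-test) under R 4.3.3. The model had 12 residual degrees of freedom, a prior of 4.19, and a biological coefficient of variation of 24.9%. P-values were adjusted by Benjamini and Hochberg over the 13442 genes within each comparison, with a threshold of 0.05. Adjusted p-values of genes are from this edgeR test and those of lists from camera or fry in limma 3.58.1. Standard errors are those of the log2 fold change from the same fit. CPM values use the TMM-scaled library sizes, log2 CPM a prior count of 2. Ratios for genes with 1 to 3 reads in a group carry a 95% interval from an exact conditional test of the 2 Poisson counts, and for groups at 0 the bound is taken against 3 counts over the group.

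Samples, comparisons, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were CX3CR1, then, per comparison and direction, up to 10 protein-coding genes with the largest absolute log2 fold change among those with adjusted p below 0.05, at least 1 CPM on average in a compared group and the same direction in at least 4 of the 5 batches. Up to 4 members of a described list with the smallest p and the 2 most abundant markers of each other cell type were added. This left 6 genes higher and 28 lower to choose from in het against control, 8 and 28 in hom against control, and 1 and 1 in hom against het. Genes of the Y chromosome and XIST were left out of all named results and plots. Gene types, and GC content for 96.5% of the tested genes, came from GENCODE 29.

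The 33 lists comprised 22 pathways and 11 sets of markers of other cell types. The pathways were homeostatic microglia, disease-associated microglia, cholesterol biosynthesis, lipid handling and efflux, lysosome, autophagy, phagocytosis, interferon response, NF-kB and cytokines, MHC class II presentation, complement, chemotaxis receptors, p53 targets with apoptosis and senescence, cell cycle, oxidative phosphorylation, mitochondrially encoded genes, glycolysis and hypoxia, unfolded protein response and amino acid stress, growth factors and neuronal support, immediate early genes, heat shock, and extracellular matrix remodelling. The other cell types were pluripotent stem cell, haematopoietic progenitor, monocyte or perivascular macrophage, granulocyte progenitor, mast cell, basophil or eosinophil, megakaryocyte or platelet, erythroid, endothelial, mesenchymal or fibroblast, neural, and dendritic cell. Lists with at least 3 tested members were tested with camera against all other genes (preset correlation 0.01), adjusted over the 27 lists tested. The correlation was also estimated from the data, and fry was run on the same fit.

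The labels say that libraries of the same number share a batch, so the numbers pair the libraries. The pairing was checked by correlating, after removal of the genotype means, the libraries of a batch: the median of 15 same-batch correlations was 0.0723 (-0.58 to 0.603, 6 of them above 0.1), against -0.0366 for 60 pairs from other batches (22 above 0.1), and 8 of 15 libraries correlated best with 1 of their own batch, against a mean of 3.02 with batch numbers shuffled within genotypes (10000 permutations, p = 0.0113). Batch was kept as an alternative (8 residual degrees of freedom) and its value is given where it changes a call. Within a genotype, pairs of replicates had log2 CPM correlations of 0.939 to 0.993, and chi-square values per gene of 10.6 to 190 showed more spread than counting error.

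Alternatives were the replicate block, only the compared groups in the fit with and without the block, DESeq2 1.42.0 size factors, upper-quartile scaling, DESeq2 tests with and without the block, limma-voom with sample weights, no filter, a filter of 1 CPM in 5 libraries, a fold threshold, and leaving out each library or batch in turn. For lists, the estimated correlation, alone and with the block, and fry were run. A correction for GC content and gene length by per-library splines with 5 degrees of freedom, with and without the block, a fit without control 1, het 3 and hom 3, and the interferon list without CMPK2 were chosen after seeing the data. For each comparison 100 of the 126 ways to divide its 10 libraries into groups of 5 were drawn and tested alike. The likeness of the het and hom changes was set against 20 simulated data sets without genotype effects and against 20 divisions of the controls. A sample was singled out when its gap to the nearest other of its group of 5 exceeded 0.71 of the group's range (Dixon's critical value).

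The procedure was tested on simulated counts with 50 genes changed per fold size. At 1.5-, 2-, 4- and 8-fold it recovered 12%, 66%, 100% and 96% of them in het against control (13332 genes in the step), 12%, 62%, 98% and 100% in hom against control (13336 genes), and 8%, 54%, 98% and 100% in hom against het (13353 genes). False calls made up 5.52%, 6.85% and 7.14% of calls. The simulation drew each gene on its own, without variation shared between genes, so these rates need not hold for the real libraries. A lysosome list raised in the simulation had the smallest p of the 27 lists tested, 2 of which were called. Individual reads, transcript isoforms and the allele of each read were not analysed here.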

Results

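Messenger RNA was sequenced from microglia-like cells that had been differentiated for 25 days from WTC11, a widely used human induced pluripotent stem cell line. 3 genotypes of this background were sampled: cells carrying the CX3CR1 V249I variant on 1 allele (het), cells carrying it on both alleles (hom), and isogenic controls without it (control). Each genotype contributed 5 libraries, numbered by a batch that it shares with the library of the same number in the other genotypes, so 15 libraries were compared. The deposited table holds read counts for 28058 genes of the GRCh38 build, and 13442 of them had enough reads to be tested. Total counts ran from 16.7 to 41.2 M per library with a median of 20.6 M. The controls held 18, 19.7, 19.2, 21.2 and 23.5 M counts, the het libraries 18.4, 24.7, 19.4, 20.7 and 21.8 M, and the hom libraries 20.6, 41.2, 16.7, 21.7 and 20 M, in batch order. The p-values of single genes and of fry below rest on the spread between these samples, which the labels call batches. Those of camera set the genes of a list against all other genes, with a preset correlation of 0.01 unless an estimated one is named. Fisher's exact test and the permutation test of neighbouring genes take genes as units, and the permutation tests of the first component and of batch shuffle libraries. Nothing in the labels states whether the batches were separate cultures. Nor do they state how many edited clones each genotype comprises, so a difference between genotypes cannot be told from a difference between clones.

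CX3CR1, the receptor through which microglia sense the neuronal chemokine fractalkine, is the edited gene and lies on chromosome 3 from 39263494 to 39281735. Its transcript was abundant in all 15 libraries. In batch order it reached 576.5, 762, 1024, 797.4 and 1026 CPM (counts scaled to the size of the library) in the controls, 918, 787.7, 354.5, 622.9 and 849.1 CPM in het, and 705.1, 750.6, 693.1, 600.9 and 706.8 CPM in hom. The group means were 837 ± 191 CPM in control, 706 ± 225 CPM in het and 691 ± 55.0 CPM in hom (SD, n = 5 each). Against control the log2 fold change was -0.25 (SE 0.22) in het and -0.28 (SE 0.22) in hom, and between hom and het it was -0.03 (SE 0.22), each with adjusted p = 1. With 1 library left out, the value against control ran from -0.3567 to -0.07527 in het and from -0.3846 to -0.1866 in hom. The sign between hom and het turned when het 1, het 2, het 5 or hom 4 was left out, with values up to 0.0803. The variant changes a single codon, so the level of this transcript checks nothing about the labels.

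**Figure D1:**
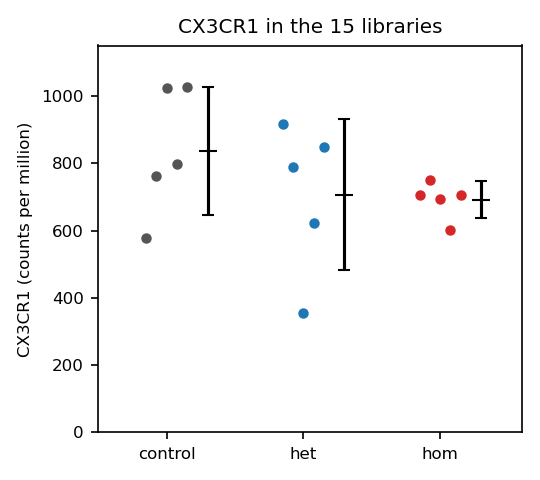
CX3CR1 level in CPM in each of the 15 libraries, by genotype. Points are libraries, and bars are the mean and SD of 5 libraries per genotype, from 691 CPM in hom to 837 CPM in control.

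The libraries differed most along an axis that did not follow genotype. The first principal component of the log2 CPM values held 46.6% of the variance, the second held 13.1%, and genotype accounted for 0.162% of the first component (permutation p = 0.99). For each library, GC correlation denotes the correlation, across genes, between the gene's deviation from the mean of all 15 libraries and its GC content. It ran from -0.685 in hom 5 to 0.729 in control 1. Genes are not independent replicates, so this value describes a library. Across the 15 libraries the first component followed it, with Pearson's r = -0.976 and Spearman's rho = -0.986 (each with permutation p = 1e-05, 2-sided, the smallest these permutations can give). Without control 1 and hom 3, the libraries farthest from the median, r was -0.975. Within genotypes it was -0.991 in control, -0.989 in het and -0.974 in hom. The first component also followed the same correlation with gene length (r = 0.872, permutation p = 5e-05, rho = 0.857, p = 4e-05) and the percentage of counts from ribosomal protein genes (r = -0.792, p = 0.00015, rho = -0.825, p = 0.0004). Without the 2 libraries farthest from the median, hom 3 and control 4 for length and hom 3 and het 3 for ribosomal proteins, r was 0.898 and -0.689. Within control, het and hom it was 0.681, 0.921 and 0.942 for length, and -0.548, -0.889 and -0.867 for ribosomal proteins. Adjusted over these 3 relations, the p-values of r were 3e-05, 7.5e-05 and 0.00015, and those of rho 3e-05, 6e-05 and 0.0004. These measures rest on the same expression values as the component, so any gene property related to it will follow it, and the p-values say nothing about its source. A batch, with 3 libraries, is too small for a value of its own.

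**Figure D2:**
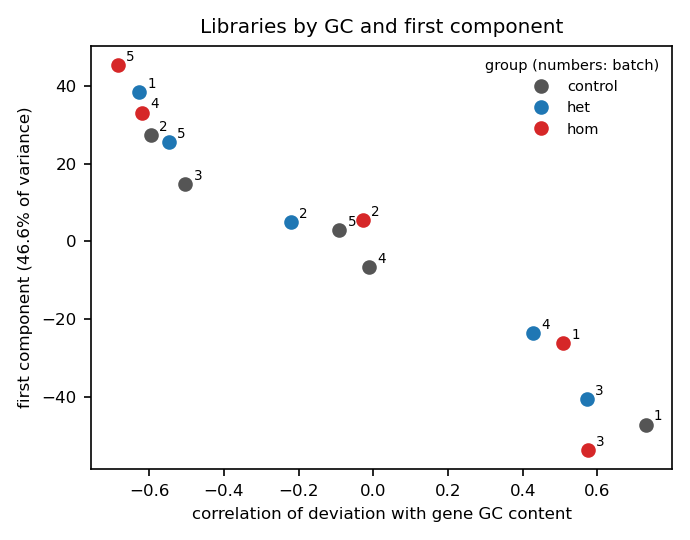
First principal component (46.6% of the variance) against the per-library GC correlation for the 15 libraries, coloured by genotype and numbered by batch. Libraries of the 3 genotypes lie along 1 line (Pearson's r = -0.976).

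The first comparison asks how cells with the variant on 1 allele differed from their controls. SAGE1, a cancer-testis antigen gene on chromosome X, rose from 1.16 ± 0.466 CPM in control to 37.7 ± 6.49 CPM in het (SD, n = 5 each). DNAJA4, which encodes a co-chaperone of the HSP40 family, fell from 14.7 ± 2.91 CPM to 0 reads in all het libraries together, at least 504-fold lower. SLC15A4, a lysosomal peptide and histidine transporter that acts in Toll-like receptor signalling, fell from 14.8 ± 3.2 to 2.45 ± 0.584 CPM. Genes of antigen presentation by MHC class II and markers of dendritic cells fell as groups. IRAK4, the kinase that relays signals from Toll-like and interleukin 1 receptors, rose from 25.1 ± 3.30 to 41.5 ± 4.88 CPM.

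In all, 42 genes were called between het and control by edgeR, 7 higher and 35 lower, and 32 of them changed by at least 1 on the log2 scale. The log2 fold change of SAGE1 was 5.02 (SE 0.28, adjusted p = 7.13e-08). Its neighbour CT45A10 rose by 4.97 (SE 0.60, adjusted p = 0.000285), though reads of this gene can be shared with near-identical members of its family. PRKCH, a protein kinase C, rose by 2.08 (SE 0.21, adjusted p = 3.17e-05) and the adhesion receptor gene ADGRG1 by 0.92 (SE 0.14, adjusted p = 0.00297). IRAK4 rose by 0.72 (SE 0.13, adjusted p = 0.0116, or 0.0569 with batch as a block) and TTC9 by 0.79 (SE 0.15, adjusted p = 0.0339, or 0.0586 with the block). Each named gene that was called in this or another comparison moved the same way in 5 of 5 batches.

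Several of the genes that fell were left with next to no reads in het. DNAJA4 had an adjusted p of 7.77e-08. GLT1D1, which encodes a protein with a glycosyltransferase domain, was at least 86.9-fold lower (adjusted p = 0.00147, or 0.0529 with the block). CMPK2, an interferon-inducible mitochondrial nucleotide kinase, was at least 53.1-fold lower (adjusted p = 0.000107). 1 read of ECHDC3 was left, a ratio of 245 between control and het (counting interval 43.6 to 9730, adjusted p = 9.27e-06), and 1 read of the protease inhibitor gene SPINK5, a ratio of 205 (36.4 to 8150, adjusted p = 4.93e-05). These bounds use 3 counts over the whole group, and bounds and intervals cover counting error only. CEBPZOS, which lies opposite CEBPZ so that the reads of the pair cannot be told apart without a known strand setting, fell by 5.28 on the log2 scale (SE 0.33, adjusted p = 1.03e-07). TSPYL5 fell by 4.67 (SE 0.39, adjusted p = 6.57e-06) and EFCAB13 fell by 4.30 (SE 0.48, adjusted p = 0.000108). The carnitine transporter gene SLC22A16 fell by 4.64 (SE 0.68, adjusted p = 0.00816, or 0.0618 with the block). It held 4 reads in het, and its log2 fold change ran from -7.547 to -4.335 under other settings. SLC15A4 fell by 2.58 (SE 0.25, adjusted p = 2.95e-05).

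**Figure D3:**
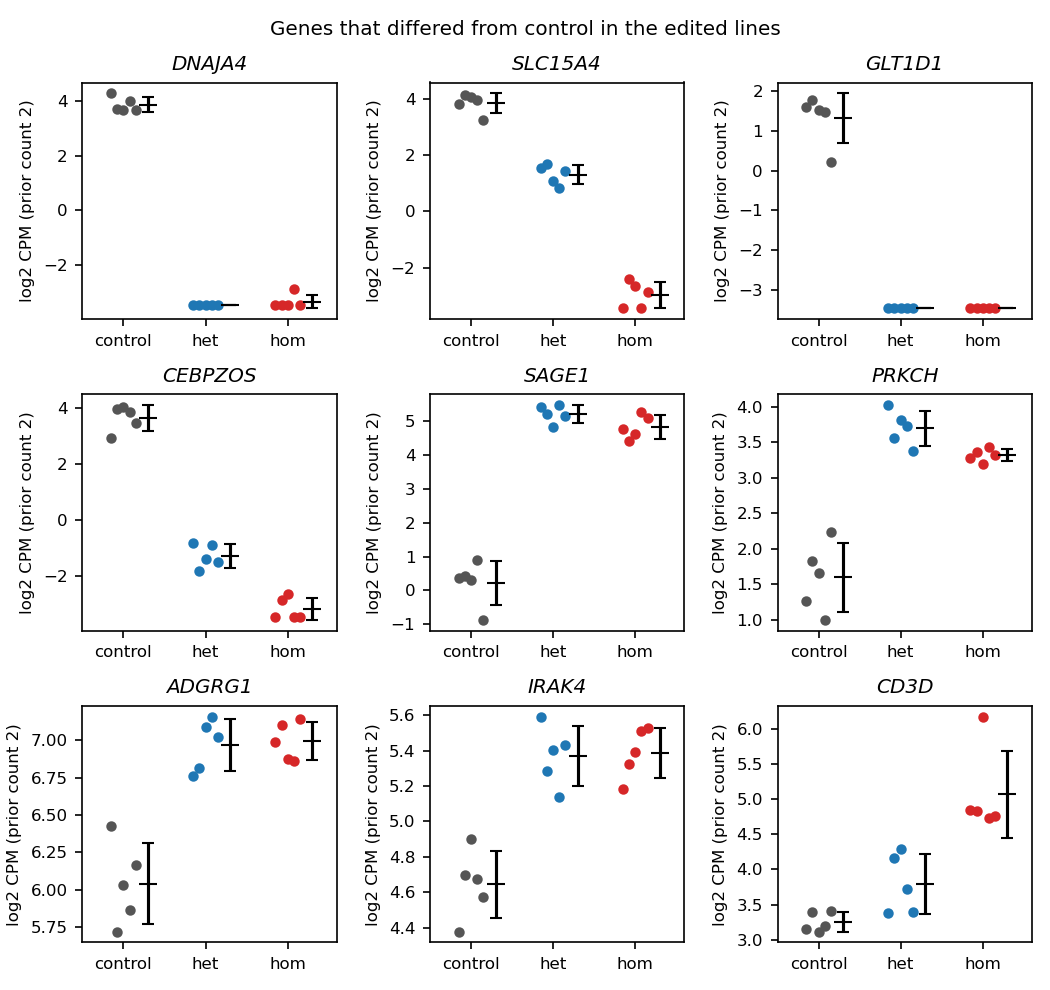
Log2 CPM (prior count 2) of 9 named genes in the 15 libraries, by genotype. Points are libraries and bars are mean and SD (n = 5 per genotype): DNAJA4 and GLT1D1 are near the floor in both edited genotypes, CEBPZOS is near it in hom, and CD3D is highest in hom.

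Among the gene lists, 6 of 27 tested moved down in het by the camera test, and none moved up. MHC class II presentation had the smallest adjusted p, 5.99e-10 (0.0145 with an estimated correlation). Of its 15 members, 14 had log2 fold changes below 0, with a median of -0.29. Over all genes 0 members were called, and 3 were when adjusted over the list alone: the co-stimulatory receptor CD40 (-0.60, SE 0.16, adjusted p = 0.0137), HLA-DQB1 (-0.48, SE 0.13, adjusted p = 0.0137) and HLA-DRA (-0.34, SE 0.11, adjusted p = 0.0379). HLA genes are near copies of each other, so how their reads divide between members is uncertain. The dendritic cell markers fell with an adjusted p of 2.68e-07 (0.0145 with an estimated correlation). All 9 tested markers were below 0, with a median of -0.30, and 0 passed over all genes while 2 passed adjusted over the list alone: the IgE receptor subunit gene FCER1A (-0.82, SE 0.20, adjusted p = 0.00644) and the lectin gene CLEC10A (-0.61, SE 0.18, adjusted p = 0.0204). The fry test, whose directional p asks whether a list's genes move on balance one way and whose mixed p asks whether they change in either direction, called the same 2 lists (directional adjusted p = 0.0111 and 0.0246).

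The disease-associated microglia list, the genes microglia raise around lesions, fell with an adjusted p of 2.76e-06 (adjusted p = 0.284 with an estimated correlation). Of its 20 members, 17 were below 0, with a median of -0.21. Over all genes 1 member passed, PLIN2, which coats lipid droplets (-0.76, SE 0.13, adjusted p = 0.0133), and 2 passed adjusted over the list alone, PLIN2 and the protease inhibitor gene CST7 (-0.96, SE 0.23, adjusted p = 0.00719). LPL (-1.13, SE 0.38) and GPNMB (-1.26, SE 0.52) did not pass. Under other settings GPNMB ran from -1.473 to -0.7588. The lysosome list had an adjusted p of 0.00319 (adjusted p = 0.446 with an estimated correlation): all 30 members were below 0, with a median of -0.12, and 0 passed singly over all genes or adjusted over the list alone. GLB1, a lysosomal galactosidase, was at -0.25 (SE 0.16) and the membrane protein gene LAMP1 at -0.19 (SE 0.14). Interferon response genes fell with an adjusted p of 4.84e-05 (adjusted p = 0.284 with an estimated correlation), 18 of 28 being below 0 with a median of -0.06. Without CMPK2, a test chosen after the values were seen, the adjusted p was 0.0249. CMPK2 and IFI44 (-1.11, SE 0.21, adjusted p = 0.0206, or 0.095 with the block) passed over all genes, and 3 members passed adjusted over the list alone with IFI44L (-1.09, SE 0.27, adjusted p = 0.00936). The immediate early genes fell with an adjusted p of 0.0182 (adjusted p = 0.284 with an estimated correlation), 15 of 19 being below 0 with a median of -0.18. 0 members passed over all genes or adjusted over the list alone, NR4A1 being at -0.42 (SE 0.21) and ATF3 at -0.33 (SE 0.17). The mixed fry test called the interferon list (adjusted p = 1.21e-05) and MHC class II presentation (adjusted p = 0.00189). With the block, 3 more lists were called down: chemotaxis receptors (adjusted p = 0.0284, against 0.0592 without it), extracellular matrix remodelling (0.0284, against 0.0682) and monocyte or perivascular macrophage markers (0.00528, against 0.0559). None of the 3 passed with an estimated correlation and no block (adjusted p = 0.33 with an estimated correlation for the first and second, adjusted p = 0.284 with an estimated correlation for the last). Of 17 tested chemotaxis receptors, FPR1, a receptor for bacterial formyl peptides, fell over all genes and adjusted over the list alone, from 109 ± 26.5 to 43.2 ± 14.9 CPM (-1.34, SE 0.23, adjusted p = 0.0116). In hom it stood at 59.8 ± 14.4 CPM (-0.87, SE 0.23), which passed only when adjusted over the list alone (adjusted p = 0.0272).

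The next comparison asks how cells with the variant on both alleles differed from control. SAGE1 reached 29.2 ± 7.18 CPM in hom against 1.16 ± 0.466 CPM in control (SD, n = 5 each), and SLC15A4 fell from 14.8 ± 3.2 to 0.0418 ± 0.042 CPM. CD3D and CD3G, which encode chains of the T cell receptor complex and lie beside each other on chromosome 11, rose to 36.6 ± 20 and 19.4 ± 4.89 CPM from 9.47 ± 0.919 and 6.97 ± 3.09 CPM. CD163, the haemoglobin scavenger receptor of perivascular and other macrophages, fell from 52.5 ± 11.2 to 25.6 ± 4.82 CPM.

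In this comparison 42 genes were called by edgeR, 8 higher and 34 lower, with 34 changed by at least 1 on the log2 scale. SAGE1 rose by 4.66 (SE 0.28, adjusted p = 4.81e-08), CT45A10 by 4.45 (SE 0.60, adjusted p = 0.00106) and PRKCH by 1.68 (SE 0.20, adjusted p = 0.000313). ADGRG1 rose by 0.94 (SE 0.14, adjusted p = 0.00199) and IRAK4 by 0.74 (SE 0.13, adjusted p = 0.00907). CD3D rose by 1.95 (SE 0.28, adjusted p = 0.00174) and CD3G by 1.47 (SE 0.28, adjusted p = 0.0315). C11orf74 rose by 1.74 (SE 0.27, adjusted p = 0.00302). Among genes that fell, DNAJA4 kept 1 read in hom, a ratio of 1750 (counting interval 314 to 69300, adjusted p = 4.81e-08), CEBPZOS 3 reads, a ratio of 532 (182 to 2580, adjusted p = 7.39e-09), and CMPK2 2 reads, a ratio of 92.4 (25.2 to 770, adjusted p = 0.000143).

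With 0 reads in hom, GLT1D1 was at least 101-fold lower (adjusted p = 0.00115), ECHDC3 at least 94.8-fold (adjusted p = 4.67e-06), SPINK5 at least 79.4-fold (adjusted p = 2.88e-05) and SLC22A16 at least 44.2-fold (adjusted p = 0.00169). SLC15A4 fell by 8.10 on the log2 scale (SE 0.39, adjusted p = 6.45e-09) and EFCAB13 fell by 3.65 (SE 0.44, adjusted p = 0.000261). HS3ST1, which encodes a heparan sulfate sulfotransferase, fell by 3.65 (SE 0.61, adjusted p = 0.00877, or 0.0645 with the block). Fitted fold changes of genes this close to 0 depend on the prior count.

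Of the 27 lists tested, 7 moved down and 2 moved up in hom against control, and with an estimated correlation 0 of these 9 calls held. The monocyte or perivascular macrophage markers had the smallest adjusted p, 5.85e-05 (adjusted p = 0.0769 with an estimated correlation). Of 7 tested markers 6 were below 0, with a median of -0.44. CD163 (-1.04, SE 0.19, adjusted p = 0.0166) was the 1 marker that passed over all genes, and the 1 that passed adjusted over the list alone, and S100A8, a calcium-binding protein of monocytes, was at -0.78 (SE 0.39). Under other settings S100A8 ran from -1.249 to -0.3433. CD163 also belongs to the phagocytosis list (adjusted p = 0.00118, adjusted p = 0.334 with an estimated correlation), of which 21 of 27 members were below 0 with a median of -0.07. CD163 was its only member to pass over all genes or adjusted over the list alone, while the Fc receptor genes FCGR2A (-0.46, SE 0.18) and FCGR3A (-0.56, SE 0.22) did not pass.

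Interferon response genes fell with an adjusted p of 0.000699 (adjusted p = 0.334 with an estimated correlation), 17 of 28 being below 0 with a median of -0.03. Without CMPK2 the list was not called (adjusted p = 0.0628), a test chosen after the values were seen. The 3 members that passed, over all genes and adjusted over the list alone, were CMPK2, IFI44 (-1.5, SE 0.21, adjusted p = 0.00127) and IFI44L (-1.49, SE 0.28, adjusted p = 0.0215, or 0.103 with the block). It was the only list called by the mixed fry test (adjusted p = 7.87e-07), and the directional fry test called 0 lists. MHC class II presentation fell with an adjusted p of 0.00145 (adjusted p = 0.184 with an estimated correlation), 10 of 15 members being below 0 with a median of -0.15. Over all genes 0 of them passed, and 1 did adjusted over the list alone, CD40 (-0.54, SE 0.16, adjusted p = 0.0455).

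The unfolded protein response and amino acid stress list had an adjusted p of 0.00542 (adjusted p = 0.184 with an estimated correlation), with 17 of 24 members below 0 and a median of -0.07. PSAT1, an enzyme of serine synthesis, was at -0.68 (SE 0.20). The list of p53 targets, apoptosis and senescence had an adjusted p of 0.0267 (adjusted p = 0.184 with an estimated correlation), with 20 of 27 below 0 and a median of -0.10, and the cell cycle inhibitor CDKN1A at -0.31 (SE 0.16). Homeostatic microglia genes had an adjusted p of 0.0467 (adjusted p = 0.455 with an estimated correlation), with 18 of 24 below 0 and a median of -0.05, GAS6 being at -0.67 (SE 0.29) and OLFML3 at -0.19 (SE 0.10). Under other settings GAS6 ran from -0.7885 to -0.3718. All 27 cell cycle genes were above 0, with a median of 0.11 and an adjusted p of 0.0294 (adjusted p = 0.673 with an estimated correlation), RRM2 being at 0.23 (SE 0.15) and PLK1 at 0.19 (SE 0.22). In these 4 lists 0 members passed over all genes or adjusted over the list alone. The 3 tested pluripotent stem cell markers were higher, with a median of 0.34 and an adjusted p of 0.0014 (adjusted p = 0.151 with an estimated correlation). 0 of them passed over all genes, and L1TD1 (1.38, SE 0.44, adjusted p = 0.0194) was the 1 that passed adjusted over the list alone. With the block the disease-associated microglia list was also called down (adjusted p = 0.0494, against 0.0612 without it, and adjusted p = 0.701 with an estimated correlation and no block). PLIN2, a member of that list, fell by 0.89 (SE 0.13, adjusted p = 0.0027) in hom, the 1 member to pass over all genes or adjusted over the list alone.

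The comparison of hom with het asks whether a second variant allele went with a further change. SLC15A4 was lower in hom than in het, at 0.0418 ± 0.042 against 2.45 ± 0.584 CPM (SD, n = 5 each), a log2 fold change of -5.51 (SE 0.41, adjusted p = 5.04e-06, or 0.000214 with the block). GPR39, a zinc-sensing receptor gene on chromosome 2, was higher in hom, at 16.1 ± 1.55 against 8.14 ± 1.53 CPM, with the controls between them at 11.8 ± 1.24 CPM. Its log2 fold change was 0.99 (SE 0.14, adjusted p = 0.0202, or 0.0747 with the block). Dendritic cell markers were higher in hom than in het as a group. In hom against control that list was not called (camera adjusted p = 0.819) and had a median of 0.07. For this list, no further move away from control was called in hom. Of its 9 tested markers, 4 were below 0 and 5 above 0 in hom against control.

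These were the 2 genes called by edgeR in this comparison. Of the 13442 genes tested, 269 had an unadjusted p under 0.05. That share is below the 0.05 that chance alone gives on average. The shares in het against control (376 genes) and hom against control (316 genes) were below it too, although 42 genes were called in each. A share of this kind therefore cannot show whether there was an excess over chance. With the block 2 genes were called, SLC15A4 and TSPEAR-AS2 (log2 fold change 1.5, adjusted p = 0.0279 with the block and 0.157 without it), an antisense gene chosen here after its values were seen. CD3D, called in hom and not in het against control, was 1.36 higher in hom than in het (SE 0.28), which did not pass (adjusted p = 0.195), and CD3G was 0.71 higher (adjusted p = 1). CD163 was lower by a log2 fold change of -0.67 (SE 0.19), which passed only when adjusted over the monocyte or perivascular macrophage list alone (adjusted p = 0.0161). FPR1, called in het and not in hom against control, was 0.47 higher in hom than in het (SE 0.23), which did not pass (adjusted p = 1).

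Against het, 4 lists were higher in hom and none was lower, and each of the 4 was called lower in het against control. Both comparisons use the same het libraries, so low values in these libraries would by themselves give both calls. The calls in het against control are therefore not independent evidence for those in hom against het. Without the block, dendritic cell markers, disease-associated microglia and immediate early genes were not called in hom against control (camera adjusted p = 0.819, 0.0612 and 0.9). All 9 dendritic cell markers were above 0, with a median of 0.27 and an adjusted p of 3.52e-08 (0.0142 with an estimated correlation). Over all genes 0 of them passed, and 4 did adjusted over the list alone: the chemokine receptor gene CCR7 (0.67, SE 0.22), LAMP3 (1.18, SE 0.40), CD1A (1.19, SE 0.42) and the Langerhans cell lectin gene CD207 (0.50, SE 0.19), each with adjusted p = 0.0357. The disease-associated microglia list was higher with an adjusted p of 0.00391 (adjusted p = 0.543 with an estimated correlation), 16 of 20 members being above 0 with a median of 0.15, CST7 at 0.80 (SE 0.23) and CD9 at 0.35 (SE 0.15). MHC class II presentation was higher with an adjusted p of 0.00241 (adjusted p = 0.303 with an estimated correlation), 13 of 15 members being above 0 with a median of 0.14, HLA-DQA1 at 0.56 (SE 0.20). The immediate early genes were higher with an adjusted p of 0.0026 (adjusted p = 0.303 with an estimated correlation), 13 of 19 being above 0 with a median of 0.14, ATF3 at 0.52 (SE 0.16) and DUSP2 at 0.44 (SE 0.17). In these 3 lists 0 members passed over all genes or adjusted over the list alone. The fry tests called 0 lists. With the block, phagocytosis (adjusted p = 0.022, against 0.0895 without it) and the monocyte or perivascular macrophage markers (adjusted p = 0.00413, against 0.0799) were also called down. Without the block neither passed with an estimated correlation (adjusted p = 0.629 with an estimated correlation and adjusted p = 0.424 with an estimated correlation).

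**Figure D4:**
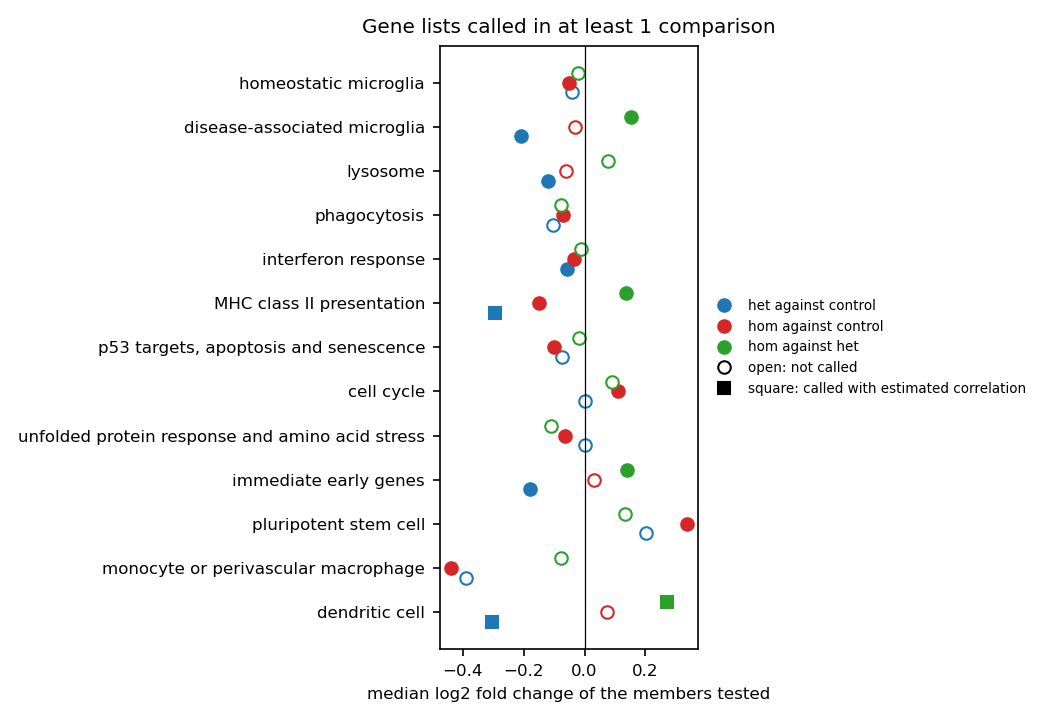
Median log2 fold change of the members of each gene list that was called in at least 1 of the 3 comparisons. Filled symbols mark lists called by camera, squares those also called with an estimated correlation, and open symbols lists not called: dendritic cell markers are below 0 in het against control and above 0 in hom against het.

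Markers of other cell types were mostly near the detection limit, with exceptions. Whether the microglia-like cells themselves or other cells among them made these exceptions was not tested. Dendritic cell markers were abundant, CD1C at 341 CPM and CD207 at 327 CPM on average over all libraries. The monocyte or perivascular macrophage markers were led by S100A9 at 162 CPM and CD163 at 39.6 CPM. PECAM1, on the endothelial list but also made by myeloid cells, reached 342 CPM while EGFL7 reached 1.54 CPM. LIN28B at 63.1 CPM and DNMT3B at 18.1 CPM led the pluripotent stem cell list, on which POU5F1 and NANOG stood at 0.04 and 0.0258 CPM. KIT at 18.2 and CRHBP at 1.18 CPM led the haematopoietic progenitor list, TREML1 at 13.4 and ITGA2B at 13.2 CPM the megakaryocyte or platelet list, and ELAVL4 at 5.57 and MAP2 at 0.283 CPM the neural list. ACTA2 at 4.98 and TAGLN at 2.06 CPM led the mesenchymal or fibroblast list, RNASE2 at 3.13 and CEBPE at 1.68 CPM the granulocyte progenitor list, and EPOR at 0.972 and KLF1 at 0.386 CPM the erythroid list. The highest gene of the mast cell, basophil or eosinophil list, PRG2, reached 0.0601 CPM.

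The lists called in none of the 3 comparisons included 14 that could be tested. The lowest of the 3 adjusted p-values was 0.159 for cholesterol biosynthesis, 0.112 for lipid handling and efflux, although its member PLIN2 fell in both edited genotypes, 0.376 for autophagy, 0.128 for NF-kB and cytokines, and 0.492 for complement. It was 0.0592 for chemotaxis receptors, 0.516 for oxidative phosphorylation, 0.159 for glycolysis and hypoxia, 0.159 for growth factors and neuronal support, 0.65 for heat shock and 0.0682 for extracellular matrix remodelling. Among other cell types it was 0.399 for haematopoietic progenitors, 0.374 for endothelial and 0.144 for mesenchymal or fibroblast markers. The granulocyte progenitor, megakaryocyte or platelet, erythroid, neural and mast cell, basophil or eosinophil lists had fewer than 3 tested members and were not tested. The 13 mitochondrially encoded genes are absent from the deposited table. Median, mean and test differed in sign in 2 lists in het against control (unfolded protein response, heat shock), in 6 in hom against control (cholesterol biosynthesis, autophagy, oxidative phosphorylation, immediate early genes, extracellular matrix remodelling, dendritic cell) and in 2 in hom against het (interferon response, chemotaxis receptors), and 0 of these were called there.

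The last comparison asks how far the changes of both edited genotypes were the same. 30 genes were called in both, 5 higher and 25 lower, and 0 moved in opposite directions. SAGE1, CT45A10, PRKCH, ADGRG1 and IRAK4 rose in both genotypes, and DNAJA4, GLT1D1, CMPK2, ECHDC3, SPINK5, CEBPZOS, SLC22A16, EFCAB13, SLC15A4, IFI44 and PLIN2 fell in both. 12 genes were called in het alone and 12 in hom alone, and these all had the same sign in the other genotype. Both comparisons use the same 5 controls, which by itself makes them alike. Independent calls would share 0.00417 genes higher and 0.0885 lower. Across all tested genes the log2 fold changes of het and hom correlated with r = 0.715, against a mean of 0.503 in 20 simulated data sets without any genotype effect, and their covariance was 0.0753 against 0.0343, a difference of 0.041. The share of genes with the same sign was 59.9%, below the 66.9% of the simulations. The correlation and covariance include the genes called in both, some with very large folds, so they cannot show a likeness of the other genes. The lower share of same signs shows none either. The simulations drew each gene on its own, without the variation between libraries that the first component holds. They cannot show how far such variation alone moves these values. With the controls divided between the comparisons, 2 against 3, over 20 assignments, the median overlap was 19 genes (16 to 20), the median correlation 0.393 (0.192 to 0.523), the median covariance 0.0511, and the median share with the same sign 39.6% (30.8% to 51.8%).

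**Figure D5:**
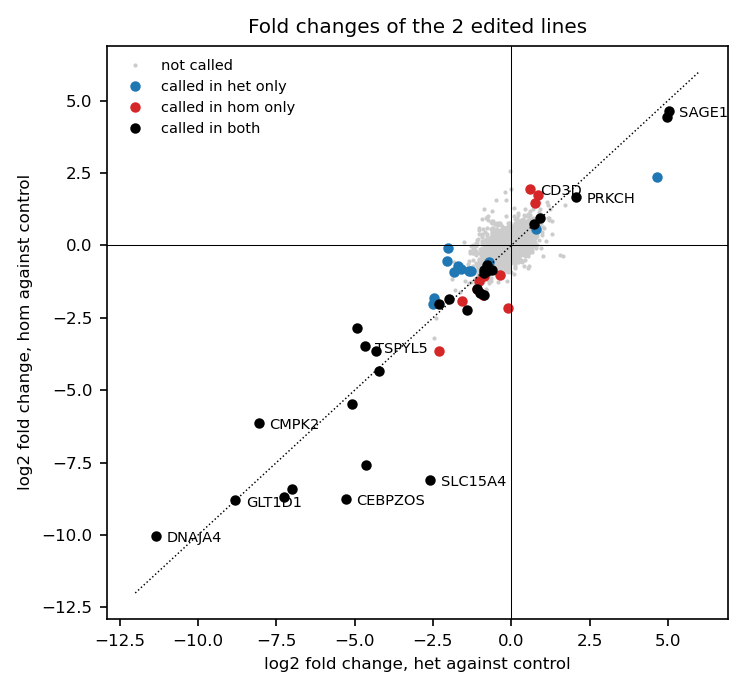
Log2 fold change against control in hom plotted against that in het for 13428 tested genes, the dotted line marking equality. Colours mark 29 genes called in both genotypes, 12 in het alone and 12 in hom alone, with genes of the Y chromosome left out; fitted values of genes near 0 reads depend on the prior count.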

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

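Of the tests weighed in this part, the splits of the libraries were chosen before the data were examined, and those of GC content or gene length, allele dose, GC composition, length, ribosomal proteins, labelled batch, T cells and the CD3 region only after the results they bear on had been seen.

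Among 66 groups of 5 values checked, 4 held a library far from the other 4, where chance gives about 1 group in 20. The total count of hom 2 was 41.2 M, against 16.7 to 21.7 M in the other hom libraries. CD3D reached 72.3 CPM in hom 3, against 26.5 to 28.7 CPM in the other hom libraries. CD3G was at 11.1 CPM in hom 1, against 19.7 to 23.2 CPM in the others. GLT1D1 was at 1.07 CPM in control 5, against 2.69 to 3.32 CPM in the other controls.

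The edited genotypes differed from each other, in a direct test of hom against het, in 2 genes and 4 lists. GPR39 had a log2 fold change of 0.986 and SLC15A4 of -5.51. The call of GPR39 was lost with the block (adjusted p = 0.0202, or 0.0747 with it) and in 7 of 15 fits with 1 library left out. The adjusted p-values of the lists were 0.00391 for disease-associated microglia, 0.00241 for MHC class II presentation, 0.0026 for immediate early genes and 3.52e-08 for dendritic cell markers, and of these the dendritic cell list alone passed with an estimated correlation (adjusted p = 0.0142).

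For the 3 counts of called genes, chance in how the libraries were divided is argued against at the 5% level only over splits drawn without regard to batch. The margin was narrow for hom against control and hom against het. With the libraries kept paired by batch, the splits cannot exclude chance at that level. For het against control, 1 of 100 splits, the real one, called as many genes as its 42, and the highest other called 0. For hom against control, 4 of 100 splits, the real one included, called at least 42, the highest other 3056, and for hom against het 4 of 100 splits, the real one included, called at least 2, the highest other 5106. These large counts point to a structure of the samples: the splits with 3056 and 5106 calls each put the 5 libraries with the lowest first component of their 10 on 1 side. Those splits part 3 of the batch pairs, and the 13, 13 and 14 splits that part all 5, as the real ones do, are too few for a share under 0.05 (42, 42 and 2 genes in the real ones, 0 in the highest other).

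Genes such as SAGE1, DNAJA4 and SLC15A4 changed in both edited genotypes. After a correction for GC content and gene length, with the block, 98.1% of the genes called in either genotype that have a GC value were still called. ZNF429 in het lost its call there with its fold nearly unmoved, from -1.82 (SE 0.36) to -1.83 (SE 0.39, adjusted p = 0.0757), as did LINC02315 in hom. GC content or gene length bias as the whole cause is thus argued against, but only for genes with smaller folds. The correction was capped in each library, so it could hardly remove folds of 3 or more on the log2 scale. Such folds were held by 16 of the 42 genes called in het, and by 16 of 42 in hom. An additive dose of the variant allele, under which het would change by about 50% of hom, is argued against by a median het change of 97% of the hom change over the genes called in hom (quartiles 82.6% and 101%), although 3 of 42 genes lay between 35% and 65%. A dominant effect of the variant and differences between edited clones unrelated to it stay open, since neither was tested and the labels do not give the number of clones.

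The libraries spread along the first component within every genotype. Labelled batch as the whole cause is argued against, since 33.4% of the variance of the component lay between batches, against a mean of 33.3% with the batch numbers shuffled within genotypes. A part played by batch stays open: the median correlation between libraries of 1 batch was 0.0723 (-0.58 to 0.603), yet 8 of 15 libraries correlated best with 1 of their own batch, against a mean of 3.02 when shuffled (permutation p = 0.0113). The relations of the component to GC content (r = -0.976), gene length (r = 0.872) and ribosomal protein genes (r = -0.792) rest on the same expression values as the component, so they decide nothing about its source. A GC composition that arises in library preparation stays open, as does a biological state of the cells, which was not tested.

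CD3D and CD3G were higher in hom than in control. T cells among the cells are argued against: CD3D rose by 27.1 CPM, and 0 of 20 other T cell genes, 6 of which are expressed highly enough here to be tested, rose by 10% of that, the highest being LCK with 0.498 CPM. CD3E, the neighbour that encodes another chain of the complex, stood at 1.85 CPM in control and 2.16 CPM in hom. A regional change around the CD3 genes is argued against, since 0% of 12 other tested genes within 250 kb rose by 0.5 or more on the log2 scale (median 0.01, highest 0.21). A change limited to the CD3D and CD3G pair stays open and was not tested.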

How the results depend on the processing

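Corrections for GC content and gene length, the fit without control 1, het 3 and hom 3, and the interferon list without CMPK2 were chosen after seeing the data. Under other settings, 117 named gene results other than those of CX3CR1 gave 2457 values. Of these, 2321 kept direction and side of the threshold, 116 no longer passed, 20 newly passed and 0 reversed. Only 61 of the 117 results were calls, and all 116 losses fell on these. The other results could count as kept by staying uncalled. The call most often lost was ZNF429 in het, in 15 of 21 settings. Of 439 values of the 19 list calls, 345 kept both and 94 no longer passed. For each change below the cause was not tested. The counts of 42, 42 and 2 called genes (het and hom against control, hom against het) became 82, 68 and 11 with DESeq2, 97, 84 and 20 with DESeq2 and the replicate block, and 16 (het) and 1 (hom against het) with the block and only the 2 compared groups. limma-voom with sample weights called 132 (het) and 6 (hom against het), GC and length correction 9 (hom against het), the same with the block 77 (het) and 7 (hom against het), and the fit without control 1, het 3 and hom 3 called 7, only the 2 groups 1 and a fold threshold of 1 on the log2 scale 1 (each hom against het). The replicate block gave 34, 38 and 2 genes, 32, 36 and 1 of them shared, and the calls it ended or made are given with the named genes; those of genes not named are left out. Leaving out 1 library gave 35 to 48, 33 to 43 and 1 to 4 genes, and leaving out 1 batch, with the block and fewer samples, 15 to 39, 16 to 37 and 1. Between hom and het 1 gene was called without het 3, het 4, het 5, hom 4 or hom 5 and 4 without hom 3. Without batch 2, 3, 4 or 5, 15, 23, 19 and 20 genes were called in het and 16, 21, 18 and 23 in hom. Of the 42, 42 and 2 called genes, 32, 31 and 1 never lost their call and 0 changed sign when 1 library of the compared groups was left out. The overlap of 30 became 19 with the controls divided. CX3CR1 between hom and het, at -0.03133, ran from -0.2014 to 0.0803 with 1 library left out (0.0803 without het 1, 0.0103 without het 2, 0.04311 without het 5, 0.01469 without hom 4) and was 0.01364 with GC and length correction and the block.

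The 6, 9 and 4 called lists became 2, 0 and 1 with an estimated correlation, 2, 1 and 1 with that and the block, and 2, 0 and 0 with fry. GC and length correction with the block gave 10 (het) and 7 (hom against het), and the fit without control 1, het 3 and hom 3 gave 7 (hom against het). Leaving out 1 library gave 5 to 11, 3 to 13 and 1 to 7: 11 without control 2, 10 without control 5 or het 1, 3 without hom 5 (hom against control), and 1 without het 5 and 7 without hom 5 (hom against het).

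With 1 library of the 15 left out, 49 of 61 calls of named genes and 7 of 19 list calls held throughout. Values in brackets are the highest adjusted p, after the library whose omission gave it. In het, PLIN2 was lost without control 5 (0.0644) or het 2, IFI44 without control 2, 3 (0.087) or 4 or het 1, 2, 3 or 4, and TTC9 without control 2 (0.126), 3, 4 or 5, het 1, 2 or 3 or hom 1, 2 or 4. In hom, CD163 was lost without control 4 or hom 2 (0.0689), 3, 4 or 5, CD3G without control 2, 3 or 4 (0.139) or hom 2, 3, 4 or 5, and IFI44L without control 1, 2 or 3 or any hom library (0.0807, hom 1). GPR39 was lost without het 1, 3, 4 (0.118) or 5 or hom 2, 4 or 5. FAM172A in het was lost without any library (0.153, control 5) but control 1, het 1 and hom 3, ZNF429 without any (0.159, het 5) but hom 3, 4 and 5, and ZNF717 in het without control 2, 3 (0.142) or 5, het 2, 3, 4 or 5 or hom 4. STOM was lost without control 2, 3, 4 or 5 or hom 1 (0.086), 2 or 3, and ZNF680 without control 2, 3 or 4 or hom 1, 2 (0.069), 4 or 5. Of the lists in het, lysosome was lost without control 1 (0.183) or het 3, and immediate early genes without control 1 (0.183) or het 3, 4 or 5. In hom, MHC class II and the unfolded protein response were lost without hom 5 (0.0608 each), pluripotent markers without control 1 (0.0708), phagocytosis without control 1 (0.107), hom 4 or hom 5, cell cycle without control 1, 3 or 5 or hom 2, 4 (0.274) or 5, p53 targets without control 2, 3 (0.104) or 4 or hom 1, 2 or 5, and homeostatic microglia without control 1, 3, 4 or 5, het 1, 2 or 4 or hom 2, 4 (0.509) or 5. Between hom and het, immediate early genes were lost without het 5 (0.0824), MHC class II without het 5 or hom 3 (0.0764) and disease-associated microglia without het 5, hom 1 (0.3) or hom 3. Without control 1, het 3 and hom 3 together, lysosome (0.511) and immediate early genes (0.251) in het and disease-associated microglia (0.235) and MHC class II (0.0522) between hom and het were not called, nor were FPR1 in het (0.109) and CD163 in hom (0.112). In that fit IFI44, PLIN2, TTC9, ZNF429 and ZNF717 in het and CD3G, HS3ST1 and IFI44L in hom lost their calls too. Depth limits genes below about 0.0247 CPM, where a group holds 3 counts or fewer.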

Other observations

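The tests of zinc finger genes, of clustering along chromosomes and of runs of neighbouring genes were chosen only after the called genes had been seen, and the test of whole chromosomes before.

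Several genes outside the rule for named genes, chosen after their values were seen, were also called against control (n = 5 each). CAT, which encodes catalase, fell by 0.86 on the log2 scale in het (SE 0.14) and fell by 0.84 in hom (SE 0.14). MRPL35, a mitochondrial ribosomal protein gene, fell by 0.88 on the log2 scale in het (adjusted p = 0.00113) and fell by 0.96 in hom (adjusted p = 0.000354). TUSC1 fell from 9.64 CPM to 3.63 CPM in het (adjusted p = 0.0023) and to 2.05 CPM in hom (adjusted p = 2.65e-05). FAM172A fell from 16.0 to 8.80 CPM in het (adjusted p = 0.0436, or 0.0938 with the block) and to 4.91 CPM in hom (adjusted p = 5.39e-05). STOM, a membrane protein gene, fell by 1.04 in hom (adjusted p = 0.0222).

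Some calls were made in 1 edited genotype. TSPEAR-AS1 and TSPEAR-AS2, antisense genes whose reads cannot be told from those of the opposite strand without a known strand setting, fell in het from 14.1 to 4.31 CPM (adjusted p = 5.25e-05) and from 6.02 to 1.47 CPM (adjusted p = 0.00163). Between hom and het TSPEAR-AS1 differed by 1.00 on the log2 scale, which did not pass (adjusted p = 0.0891). SPATA22, below 1 CPM in all groups, rose in het to 0.633 CPM from 2 reads in control, a ratio of 32.3 (counting interval 8.59 to 272, adjusted p = 0.00113). In hom it held 14 reads, 0.147 CPM, a ratio of 5.91 to control (1.36 to 53.6) that did not pass over the replicates (adjusted p = 1), and the difference between hom and het did not pass either (-2.31, adjusted p = 0.185). ZNF350 fell from 2.66 to 0.657 CPM in het (adjusted p = 0.00459) and stood at 2.54 CPM in hom, a difference between the genotypes of 1.95 that did not pass (adjusted p = 0.0566).

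Whether zinc finger genes are over-represented among the called genes cannot be told. Of 55 genes called in any comparison 5 had ZNF symbols, against 460 of the 13442 tested (odds ratio 2.84, Fisher's exact test, 1-sided, p = 0.0394), and all 5 fell: ZNF350, ZNF429 (-1.82, adjusted p = 0.0426, or 0.0805 with the block) and ZNF619 (-1.28, adjusted p = 0.00508) in het, ZNF680 in hom (-2.18, adjusted p = 0.0176, or 0.0956 with the block), and ZNF717 in both (-1.01, adjusted p = 0.0339, or 0.095 with the block, and -1.63, adjusted p = 0.00035). With the block 3 of 49 called genes had ZNF symbols (odds ratio 1.85, Fisher's exact test, 1-sided, p = 0.235).

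Called genes may cluster along chromosomes. Among 54 genes called in either edited genotype, 7 pairs lay within 1 Mb of each other, against a mean of 2.05 and a highest of 9 in 10000 random sets matched on expression (permutation p = 0.0041). Among the pairs were IFI44L and IFI44, CD3D and CD3G, SLC15A4 and GLT1D1, FPR1 and ZNF350, TSPEAR-AS1 and TSPEAR-AS2, and CT45A10 and SAGE1. A gain or loss of a whole chromosome in 1 genotype is argued against for chromosomes 1 to 22 and X. The largest shift of any of their medians relative to the others was 0.0296 in size on the log2 scale. The Y chromosome was left out of this test. For chromosome arms, runs of 50 neighbouring genes at a single position and with mean log2 CPM above 2 were used. The largest shift of a run's median was 0.0919 in size, which argues against a gain or loss of arms that hold a full run.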
